A study of Mus musculus with 24 samples.

How the data were processed

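Thymus RNA of 24 mice was measured on 2-colour Agilent 4x44K mouse arrays, 6 each of wild type, p27 knockout, stathmin knockout and double knockout. Per the labels the mice were separate biological replicates, RNA was isolated on columns, amplified and labelled by amino-allyl coupling, the thymus carried Cy5 and a common pool of fibroblast RNA of all genotypes carried Cy3, in the same orientation on every array. Groups and replicate numbers were taken from the labels. The labels gave 3 females and 3 males per genotype without saying which mouse was which, so sex was not a term in any fit.

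The authors deposited a scanner file per array. Spot and local background intensity of both channels was extracted by the authors with Agilent Feature Extraction 9.1.3.1, per the file headers, by a protocol without background subtraction. The deposited log10 ratios (Cy5 over Cy3) had been spatially detrended and dye-normalized with a linear and lowess step, per the file headers. A deposited table of log2 values for all 24 arrays also came from the authors, and all 24 of its columns were used. How it was made is not given in the sources used here. Each of its columns correlated by at least 0.9795 with the mean log2 of both channels and by at most 0.0692 with the log2 ratio of the same array, so it follows the brightness of a spot and not its ratio, its scale is log2 and its centring stays unknown. Its column medians, replicates 1 to 6, were 9.28, 9.35, 9.33, 8.66, 9.74 and 9.23 for wild type, 8.75, 8.74, 8.90, 9.11, 8.73 and 8.62 for the p27 knockout, 10.6, 9.45, 8.88, 9.10, 9.18 and 9.20 for the stathmin knockout, and 9.40, 9.32, 9.46, 9.17, 9.15 and 9.30 for the double knockout. It served as an alternative only.

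From the intensities, log2 ratios were computed with limma 3.58.1 in R 4.3.3 (files read with the data.table package, version 1.17.8). The background was corrected with normexp (offset 50), control spots were given no weight, each array was normalized within itself by loess, spots marked as outliers by the scanner software were left out (68 per array on average, at most 314), and spots of 1 probe were averaged. No scaling between arrays was applied. Of 45018 spots per array, 41174 were gene probes. The accessions of 22951 probes matched the gene table given with assembly GRCm38.p6 and took its symbols, and 18223 kept the name in the file. That table was otherwise used only for the order of genes along chromosomes. A probe was kept where its Cy5 signal was well above background on at least 6 of the 24 arrays (35185 probes), and the brightest probe stood for each gene (24784 genes). Of 7397 genes with several probes, 3415 had probes that differed in sign in the double against the p27 knockout. Across the 5200 genes with 2 probes that comparison's changes correlated by 0.399, with 62.1% of the same sign. For a probe not well above background on every array of a group, only a lower bound of the fold is given, against the lowest signal well above background on each array. It compares single channels and is open to dye bias, since no dyes were swapped. Between 61.9% and 90.9% of Cy5 spots per array were well above background, and no pair of arrays held identical signals (0 pairs).

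The test was limma's moderated test on all 24 arrays, which share 1 estimate of the spread, with genotype as the only term and Benjamini-Hochberg adjustment over all genes (threshold 0.05). The 5 comparisons were each knockout against wild type and the double against each single knockout, and the interaction tested departure from additivity. All adjusted p values of genes are limma's. Gene lists, 11 gene groups and 16 cell types, were tested with limma's camera (preset correlation 0.01) and adjusted over the 27 lists, with an estimated correlation as an alternative. The gene groups were G1/S, G2/M, cyclin-dependent kinases, stathmin and tubulins, p53 targets, histones, interferon, T cell receptor signalling, stress, ribosomal proteins and oxidative phosphorylation. The cell types were those of thymocytes, other blood cells, thymic epithelium, fat, muscle, fibroblasts, vessels, parathyroid and thyroid and lymph node stroma. Counts adjusted over the list alone use only the members of a list.

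The design, the lists, the alternatives listed next and the rule for named genes were fixed before the data were examined. That rule named Cdkn1b and Stmn1, the 8 largest rises and 8 largest falls among passing genes whose 6 arrays of 1 genotype all lay on the same side of the other genotype's mean (leaving out Xist, Tsix, Y-linked genes and predicted or clone names), the 3 members with the lowest p in the direction of each shifted list, the 2 members with the lowest p of the G1/S, G2/M, cyclin-dependent kinase and stathmin lists, and for the interaction 5 genes each way.

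Alternatives were no background correction, Agilent's own log ratios centred on the median, the Cy5 channel alone with quantile normalization, the authors' deposited table, a filter on both channels, the mean of a gene's probes, only the 2 genotypes compared, array weights, the replicate number, slide or scan day as a block, and each array left out in turn. Slide and scan day (3 days of 2 slides each) came from the file headers. After the data had been seen, 3 more were added: p27 knockout replicates 5 and 6 left out, the log2 brightness of each array as a covariate, and slide as a block together with array weights.

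The fit was tested on simulated data with 24784 genes, of which 200 were changed by known amounts. For log2 changes of 0.5, 1 and 2, the share recovered was 0%, 17.9% and 77.3% for the p27 knockout against wild type, 1.49%, 29.9% and 81.8% for the stathmin knockout, 2.99%, 23.9% and 78.8% for the double knockout, 1.49%, 26.9% and 83.3% for the double against the p27 knockout, and 1.49%, 26.9% and 83.3% for the double against the stathmin knockout. All 3 shifted lists were found in each comparison, and 1 unshifted list was also called in the stathmin knockout against wild type and 1 in the double against the p27 knockout. Of the genes called, 8.70%, 5.06%, 9.09%, 7.50% and 7.50% were unchanged ones, in the same order. The noise was drawn independently for each gene, so the genes of a list did not vary together. These rates of false calls therefore do not carry over to the real arrays. There, other splits of the mice of each pair shifted a median of 11, 10, 9, 12 and 9 of the 27 lists, in the same order.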

Results

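Thymus RNA of 15-week-old C57BL/6 mice of 4 genotypes was measured on 24 microarrays, 6 mice per genotype. The genotypes were wild type, p27 knockout (without Cdkn1b, which encodes p27Kip1, an inhibitor of the cyclin-dependent kinases that drive the cell cycle), stathmin knockout (without Stmn1, whose product destabilises microtubules) and double knockout (without both). The labels gave 3 females and 3 males per genotype but not the sex of each mouse. The study asked how p27 and stathmin together control cell proliferation in the animal. Each array read a thymus in the Cy5 channel against 1 common pool of fibroblast RNA in the Cy3 channel, so a log2 ratio is the thymus level relative to fibroblasts. After filtering, 24784 genes were tested, and the 24 arrays and 6 mice per genotype limited the precision. The arrays lay on 6 slides, each with 1 array of every genotype at the same position, so position and genotype cannot be told apart.

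The p27 knockout arrays were dimmer than the rest. The 99th percentile of Cy5 intensity, in kilo-units, was 86.4 ± 53.2 (SD, n = 6) for the p27 knockout, 190.6 ± 92.0 for wild type, 239.5 ± 71.8 for the stathmin knockout and 247.8 ± 45.1 for the double knockout. Replicates 6 and 5 of the p27 knockout were dimmest, at 19.4 and 50.7. Their log2 ratios correlated across genes with those of the other 23 arrays by 0.205 and 0.587 on average, against 0.778 to 0.865 for the remaining 22 arrays. In the p27 knockout replicate 6 the thymocyte genes stood near the fibroblast level, with a median log2 ratio of 0.08 for markers of double-positive thymocytes against 5.24 to 6.17 in the other 5 p27 knockout mice. Each comparison with the p27 knockout was therefore also made without replicates 5 and 6.

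**Figure D1:**
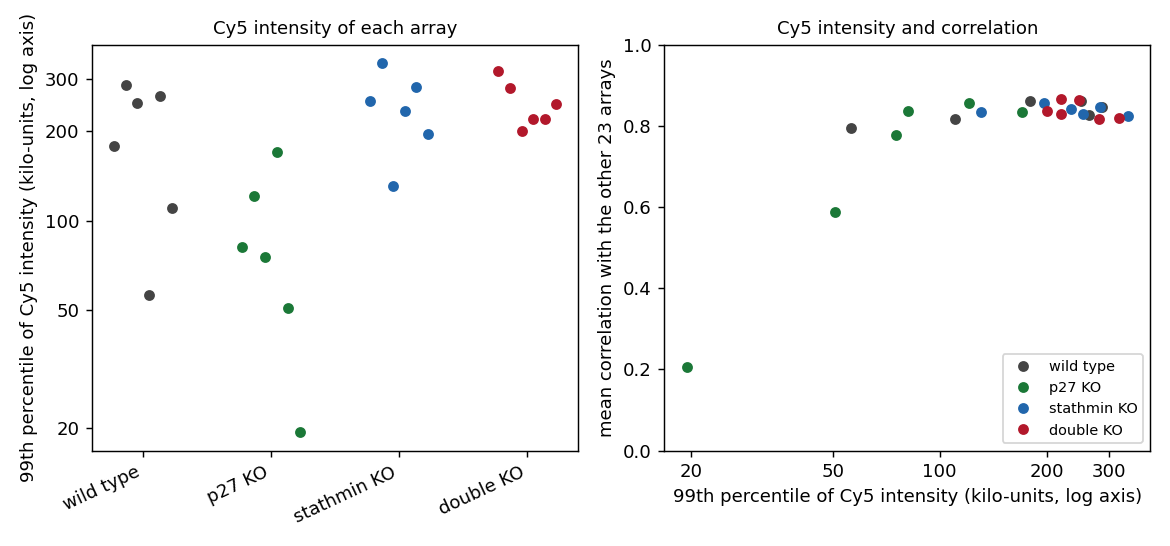
Left, the 99th percentile of Cy5 intensity (kilo-units, log axis) of each of the 24 arrays by genotype; right, the same value against the mean correlation across genes of each array's log2 ratios with the other 23. Each point is 1 array, and the p27 knockout arrays with intensities of 19.4 and 50.7 have the lowest correlations, 0.205 and 0.587.

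Stmn1 RNA fell in both genotypes that lack it, on a probe that separated them from the others on 6 of 6 slides. On probe A_52_P319161 the log2 ratio was 3.1 ± 0.28 (SD, n = 6) in wild type, 2.45 ± 0.87 in the p27 knockout, -2.94 ± 0.75 in the stathmin knockout and -3.19 ± 0.36 in the double knockout. Stmn1 fell by 6.05 ± 0.34 (SE) in the stathmin knockout against wild type, 66.0-fold (limma adjusted p = 2.04e-10, and 6.22e-09 with slide as a block). It fell by 6.29 in the double knockout against wild type (adjusted p = 8.67e-11) and fell by 5.64 against the p27 knockout (adjusted p = 9.19e-10). A brighter Stmn1 probe, A_51_P495641, read 3.55 ± 0.26 in wild type, 2.82 ± 1.78 in the p27 knockout, 2.01 ± 0.25 in the stathmin knockout and 1.88 ± 0.54 in the double knockout. On that probe, which stands for Stmn1 in the gene-level counts, the differences from wild type were -1.54 and -1.67, below 0 on 6 of 6 slides, and did not pass (gene-level adjusted p = 1.00 and 0.387). Without p27 knockout replicates 5 and 6 the same differences had adjusted p = 0.00991 and 0.00292, while in the authors' deposited table they were 0.11 and 0.08. That table follows the mean brightness of both channels and not the ratio. Here and below its values are therefore not a like measure of the changes beside them.

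Cdkn1b RNA was lower in both genotypes that lack p27. On probe A_51_P146126 the log2 ratio was 1.80 ± 0.35 (SD, n = 5) in wild type, 0.30 ± 0.57 (n = 6) in the p27 knockout, 1.64 ± 0.40 (n = 6) in the stathmin knockout and -0.50 ± 0.88 (n = 5) in the double knockout. Cdkn1b fell by 2.30 ± 0.36 (SE) in the double knockout against wild type, 4.91-fold (gene-level adjusted p = 0.0360), and by 2.14 ± 0.34 against the stathmin knockout, 4.42-fold (gene-level adjusted p = 0.0350, and 0.0529 over all probes). Both were lower on 5 of the 5 slides with both values, but adjusted p was 0.0818 and 0.267 with slide as a block. On the remaining slide the spots of wild-type and double knockout replicate 1 were left out as outliers. Raw Cy5 was 27150 and 22650 there, on arrays with 99th percentiles of 179 and 320 kilo-units. In the authors' deposited table the fall against wild type was -0.46 (adjusted p = 0.620). The difference of -1.49 ± 0.34 between the p27 knockout and wild type did not pass (adjusted p = 0.0812, 5 of 5 slides below 0). A probe with 10 spots, A_51_P169173, was well above background on 6 wild-type, 5 stathmin knockout, 1 p27 knockout and 0 double knockout arrays. Wild type was at least 1.77-fold and the stathmin knockout at least 2.03-fold above the double knockout there (adjusted p = 0.248 and 0.556). The remaining probe, A_52_P673863, was near background, at -0.50, -0.99, -0.54 and -0.61 in wild type, p27, stathmin and double knockout. Which parts of Cdkn1b and Stmn1 were deleted is not given in the sources used here, so a probe that keeps its signal checks nothing.

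**Figure D2:**
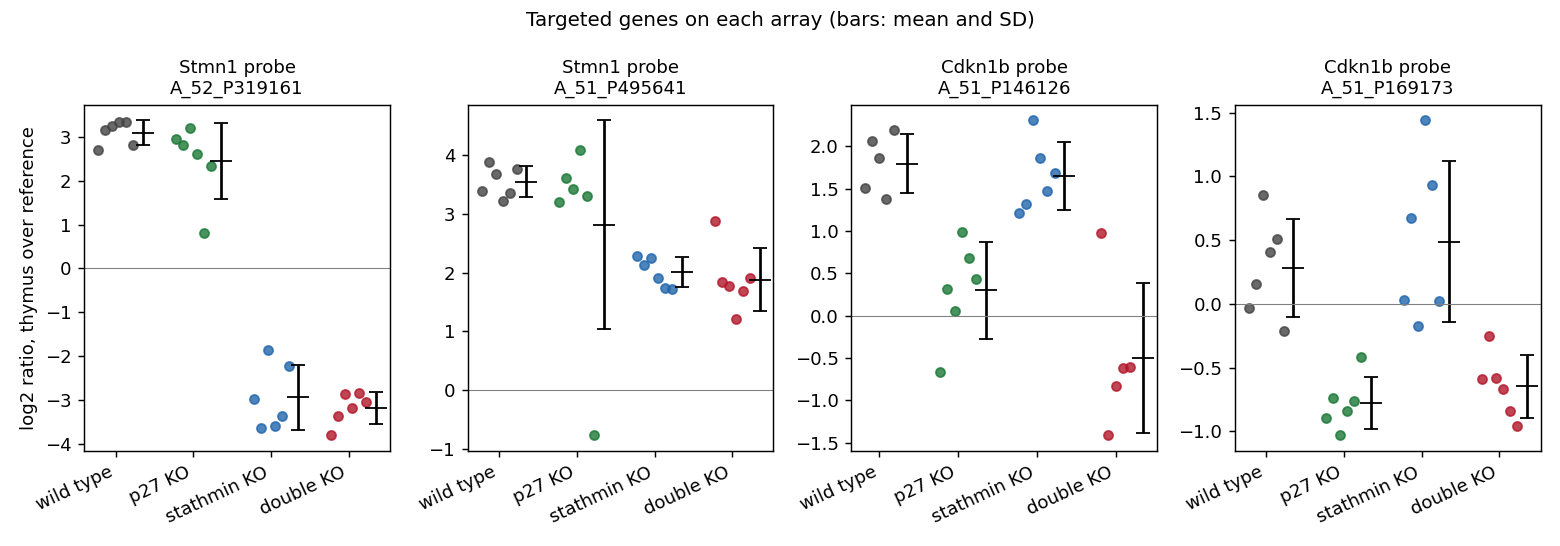
Log2 ratio of thymus over the fibroblast reference for 2 probes of Stmn1 and 2 of Cdkn1b, with 1 point per array and genotype and bars for the mean and SD. Stmn1 probe A_52_P319161 lies at 3.1 in wild type and at -2.94 and -3.19 in the stathmin and double knockouts, and Cdkn1b probe A_51_P146126 at 1.80 in wild type and 0.30 and -0.50 in the p27 and double knockouts.

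Loss of p27 alone was examined against wild type. Klra10 and Klra9, which encode Ly49 receptors of natural killer cells, were the 2 genes that passed, and both fell in the p27 knockout. Klra10 fell by 2.83 ± 0.46 (SE), 7.08-fold, from 3.36 ± 0.62 (SD, n = 6) to 0.53 ± 0.40, and Klra9 fell by 2.63 ± 0.41, 6.19-fold, from 3.58 ± 0.62 to 0.95 ± 0.35 (limma adjusted p = 0.0306 for each). Both were lower on 6 of 6 slides, by -3.91 to -2.00 and -3.59 to -1.52. They lie 24 and 26 measured genes from Cdkn1b on chromosome 6 in the gene order of assembly GRCm38.p6. Neither passed with slide as a block (adjusted p = 0.0634 for each), nor without p27 knockout replicates 5 and 6 (adjusted p = 0.128 and 0.0937), where the changes stayed at -2.74 and -2.58. Among the cell cycle genes, Ccne1 (cyclin E1), E2f1 and Foxm1, which promote entry into S phase and mitosis, read 0.68, 0.60 and 0.65 higher, and Pcna, Cdc45 and Ttk, of replication and the spindle checkpoint, -0.97, -1.53 and -0.93. None of these passed (adjusted p = 0.0812, 0.0862, 0.0812, 0.0883, 0.0969 and 0.0850), and in the authors' deposited table Ccne1, E2f1 and Foxm1 were at -0.44, -0.65 and -0.54. The tubulin genes Tubb6 and Tubb3 read 1.24 and 1.15 higher (adjusted p = 0.0812 for each), against -0.16 and -0.30 in that table.

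Of 24784 genes, 2 passed in this comparison and 7182 had an unadjusted p under 0.05, where about 1239 would by chance. With slides as blocks limma passed 0 genes and 7849 had an unadjusted p under 0.05, and without p27 knockout replicates 5 and 6 it passed 4, none of them among the 2. The authors' deposited table had 4444 genes lower and 1 higher, whereas array weights gave 2236 higher and 502 lower, and slide as a block plus weights 3395 higher and 1090 lower. The count was 0 without any 1 of wild-type replicates 1, 2, 3 and 5, p27 or stathmin knockout replicate 3 or double knockout replicate 6, and 4 without p27 knockout replicate 6 or stathmin knockout replicate 1. It was 5 without wild-type replicate 4, 2413 without wild-type replicate 6, and 1628, 2563 and 2833 without p27 knockout replicates 2, 1 and 4. The median change over all genes was 0.15, and -0.55 in the authors' deposited table, where it was 0.68 rather than -0.16 for the double against the p27 knockout, 0.13 rather than -0.02 for the stathmin knockout and 0.14 rather than -0.04 for the double knockout against wild type.

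Of 27 gene lists, 12 shifted in the p27 knockout against wild type, 1 up and 11 down, and all 12 shifted with slide as a block. There were 8, 4 up and 4 down, without p27 knockout replicates 5 and 6, and with brightness as a covariate 1, up. No list passed with an estimated correlation (adjusted p = 0.731 at the lowest). Fibroblast and extracellular matrix genes were higher as a set, with a median change of 1.04 and 22 of 24 members above 0 (camera adjusted p = 8.60e-05, and adjusted p = 0.731 with an estimated correlation). No member passed over all genes, and 16 rose adjusted over the list alone. The leading members were Pdgfrb, a receptor of mesenchymal cells, at 0.76, Serpinf1 at 1.40 and Fn1 (fibronectin) at 1.36, all with adjusted p = 0.0812, and at -0.38, -0.05 and -0.06 in the authors' deposited table. On single slides the list's median ran from -0.26 to 3.39 and was above 0 on 4 of 6, adjusted p was 7.95e-05 with slide as a block, and without p27 knockout replicates 5 and 6 the median was 0.50 (adjusted p = 0.0256). The list's median log2 ratio per array was -1.92 ± 1.03 (SD, n = 6) in the p27 knockout and -2.92 ± 0.54 in wild type, and the p27 knockout arrays carried the lower Cy5 signal.

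Adipocyte genes were lower as a set in the p27 knockout, with a median change of -0.77 and 21 of 24 members below 0 (adjusted p = 8.60e-05, slide-blocked 7.36e-05, and adjusted p = 0.731 with an estimated correlation). The slide medians ran from -3.40 to 0.08, with 5 of 6 below 0. Scd1, which desaturates fatty acids, was at -2.12, and Retn and Cd36 at -1.49 and -1.54 (adjusted p = 0.0812, 0.101 and 0.118). Genes of oxidative phosphorylation (median -0.14, adjusted p = 0.00319, slide-blocked 0.00162) and ribosomal protein genes (median -0.30, adjusted p = 0.000624, slide-blocked 0.000872) were also lower on 4 of 6 slides each (adjusted p = 0.731 with an estimated correlation). In the authors' deposited table ribosomal protein genes were higher relative to other genes (adjusted p = 1.22e-05). Sdhb and Sdha of respiratory complex II were at -1.01 and -1.10 and Rpl4 at -1.40, none past the threshold. These 3 lists shifted the same way without p27 knockout replicates 5 and 6 (adjusted p = 0.0140 for adipocyte, 0.0169 for oxidative phosphorylation and 0.0256 for ribosomal protein genes). The median changes were then smaller, at -0.05 for oxidative phosphorylation and -0.10 for ribosomal protein genes.

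Proliferation and immune lists made up the other 8 lower sets. Their medians were -0.20 for G1/S and replication, -0.19 for G2/M, -0.49 for double-positive, -0.39 for double-negative and -0.39 for mature T cells, -0.47 for natural killer and gamma delta T cells, -0.61 for B cells and -0.31 for macrophages. The adjusted p values were 0.0197, 0.0320, 0.0136, 0.0197, 0.0272, 0.0272, 0.0164 and 0.0285, and 0.0223, 0.0271, 0.0163, 0.0223, 0.0271, 0.0303, 0.0163 and 0.0257 with slide as a block (adjusted p = 0.731 with an estimated correlation for each). The leading members, none past the threshold, included Cd4 at -1.59, Runx3, a regulator of CD8 T cells, at -1.18, Xbp1, needed for plasma cells, at -1.27 and Spi1, a myeloid regulator, at -1.34. All of these lists except B cells were lost without p27 knockout replicate 6, with the lowest brightness. Without replicates 5 and 6 double-positive thymocyte genes were higher instead (median 0.48, adjusted p = 0.0256), as were T cell receptor signalling (0.30, 0.0169) and cortical epithelial genes (0.34, 0.0256). The G1/S and G2/M medians were then 0.24 and 0.17, not past the threshold (adjusted p = 0.153 and 0.384). Those of double-negative, mature T and natural killer genes were 0.08, 0.07 and 0.03. On all arrays the G1/S and G2/M medians were below 0 on 3 of 6 slides each. On single slides the double-positive median was above 0 on 5 of 6, from -5.35 to 1.11. The B cell list was lost without wild-type replicate 2 (adjusted p = 0.114), G1/S genes without wild-type replicate 4 and G2/M genes without it or p27 knockout replicate 5 (adjusted p up to 0.655 and 0.965 over single mice left out). Mature T, natural killer and macrophage genes were lost without wild-type replicate 1 or 2, and macrophage genes also without wild-type replicate 5 (up to 0.687, 0.433 and 0.652).

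**Figure D3:**
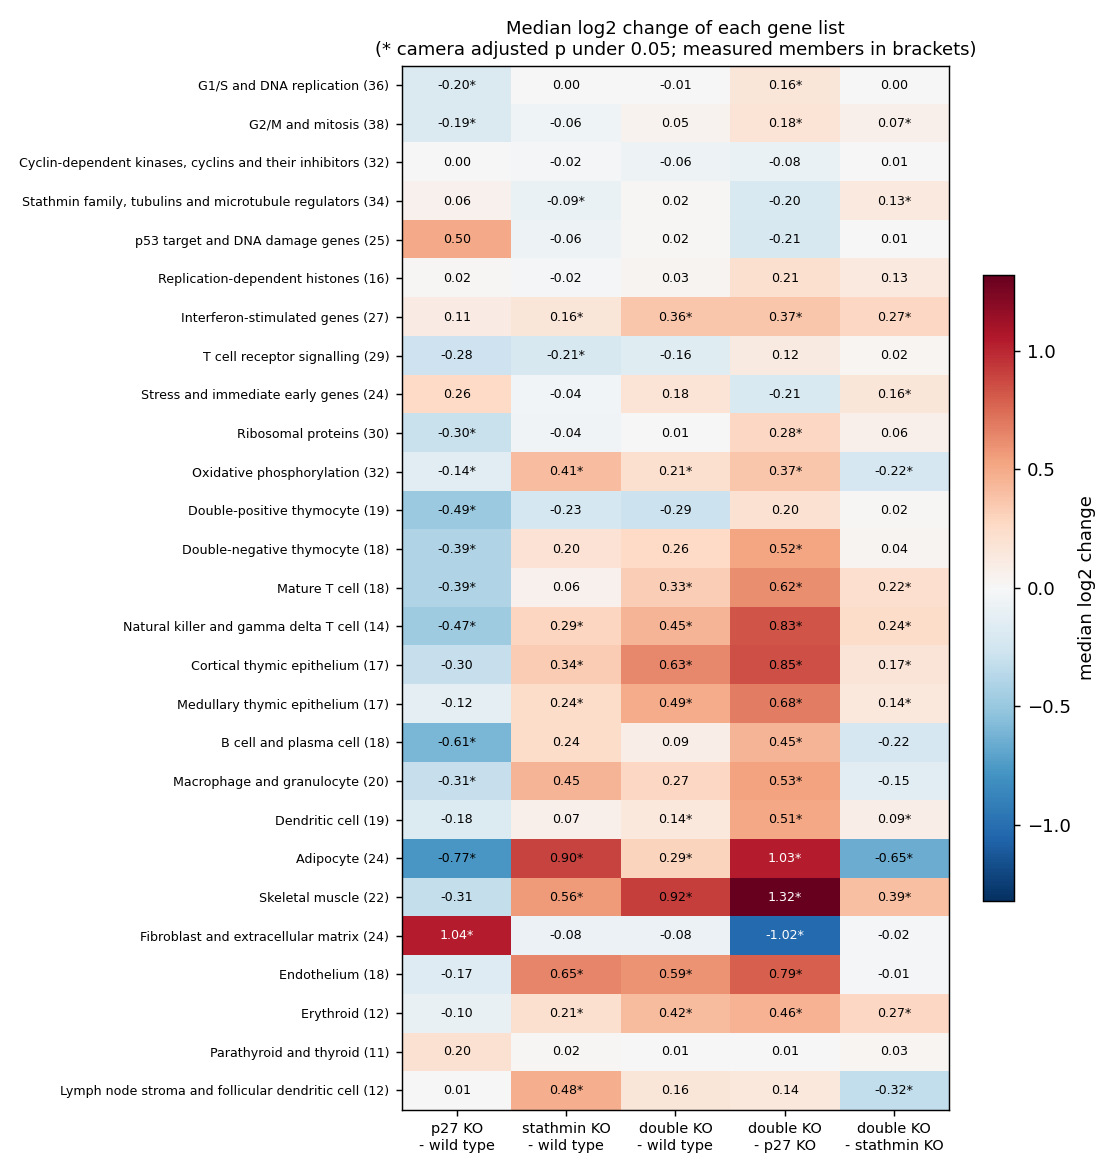
Median log2 change of each of the 27 gene lists (rows, measured members in brackets) in the 5 comparisons (columns), with red above 0, blue below 0 and a star where camera's adjusted p is under 0.05. Fibroblast genes stand at 1.04 in the p27 knockout against wild type and -1.02 in the double against the p27 knockout (upward in the authors' deposited table, not past the threshold), and endothelial genes at 0.65, 0.59 and 0.79 in the stathmin knockout and double knockout against wild type and the double against the p27 knockout.

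**Figure D4:**
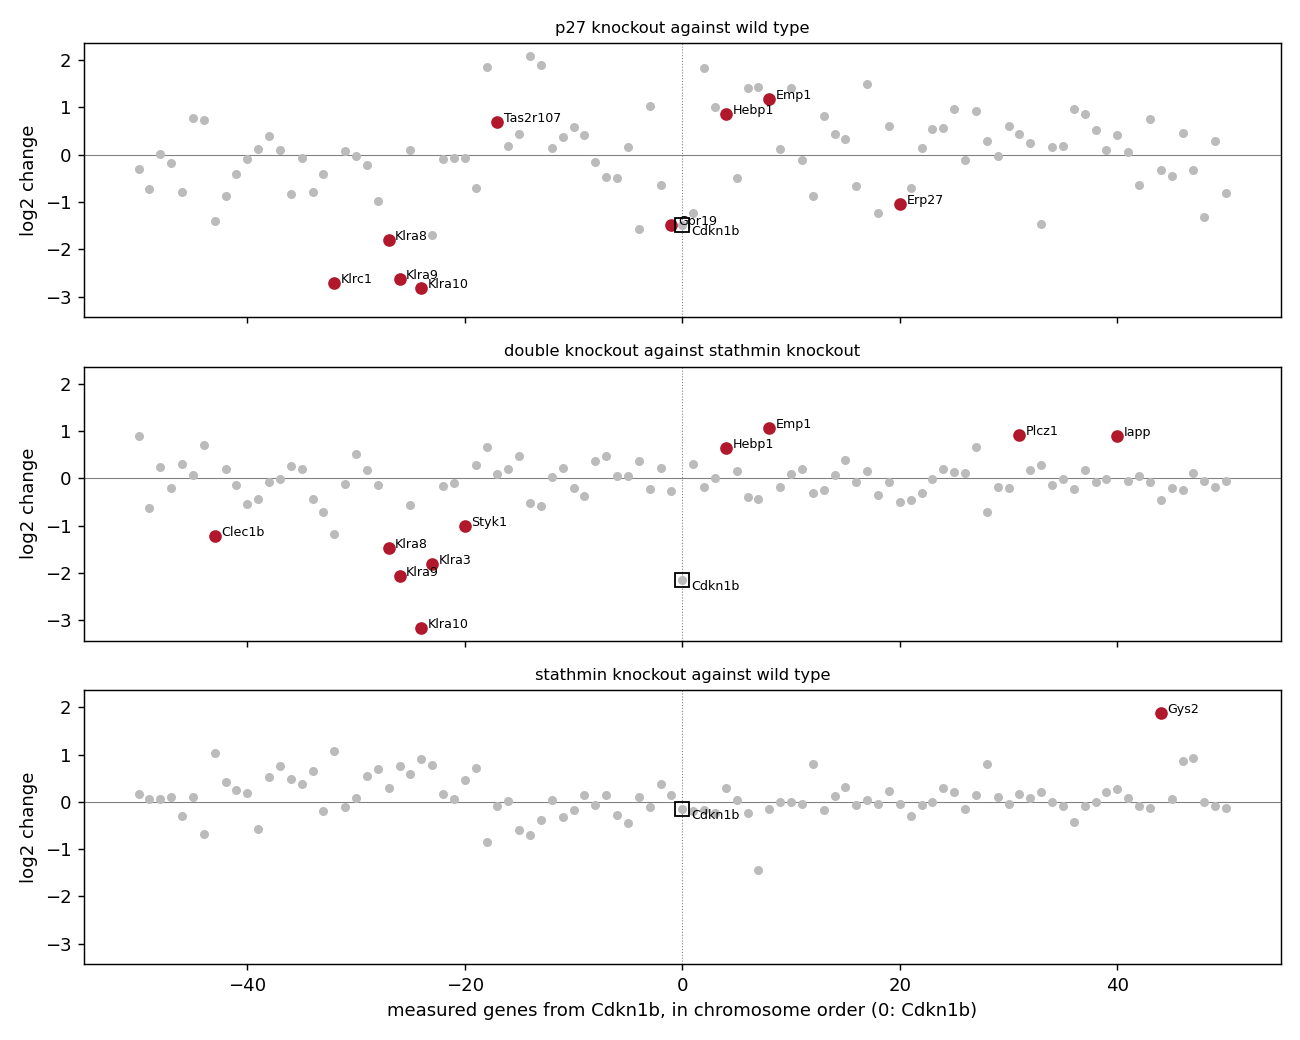
Log2 change of the 50 measured genes on each side of Cdkn1b on chromosome 6, in chromosome order, for p27 knockout against wild type, double against stathmin knockout and stathmin knockout against wild type; each point is 1 gene, red points are among the 100 genes with the lowest p of that comparison and the open square is Cdkn1b. Klra10 stands at -2.83, -3.17 and 0.91 in the 3 panels, and 9, 10 and 1 neighbours are red.

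Loss of stathmin alone was examined against wild type. Genes of oxidative phosphorylation, the mitochondrial chain that makes ATP, were higher in the stathmin knockout as a set, with a median change of 0.41 and 31 of 32 members above 0 (camera adjusted p = 2.86e-23, slide-blocked 4.51e-23). The list's median was above 0 on 6 of 6 slides, from 0.20 to 0.91, and adjusted p = 0.124 with an estimated correlation. Ndufa1, Cox7b and Atp5b, subunits of complexes I and IV and of ATP synthase, were at 0.89, 0.77 and 0.52, above 0 on 6 of 6 slides, with Atp5b at -0.01 in the authors' deposited table. Adipocyte genes were higher as a set (median 0.90, 24 of 24 above 0, adjusted p = 2.89e-18, slide-blocked 1.67e-19, and adjusted p = 0.124 with an estimated correlation), on 5 of 6 slides, with medians from -0.08 to 1.60. Elovl3 and Scd1, enzymes of fatty acid synthesis, were at 2.02 and 2.09 on 6 of 6 slides above 0, and Pnpla2, the lipase that starts triglyceride breakdown, at 1.43. No adipocyte gene passed over all genes and 4 rose adjusted over the list alone. Endothelial genes were higher as a set (median 0.65, 18 of 18 above 0, adjusted p = 5.99e-10, slide-blocked 2.52e-10, and adjusted p = 0.167 with an estimated correlation), from -0.39 to 1.52 on single slides with 5 of 6 above 0. The vessel genes Ptprb, Emcn and Sox17 were at 1.00, 0.99 and 0.92.

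Further upward shifts in the stathmin knockout covered markers of cortical thymic epithelium (median 0.34, adjusted p = 0.00541, 6 of 6 slides), interferon-stimulated genes (0.16, 0.00541, 5 of 6), natural killer and gamma delta T cells (0.29, 0.0101, 5 of 6), lymph node stroma (0.48, 0.0120, 5 of 6), medullary thymic epithelium (0.24, 0.0206, 3 of 6), skeletal muscle (0.56, 0.0211, 3 of 6) and erythroid cells (0.21, 0.0410, 4 of 6). Their adjusted p values with slide as a block were 0.00790, 0.00790, 0.00884, 0.00884, 0.0348, 0.0148 and 0.0348. Their leading members included the interferon-induced Ifi27 at 1.03. Adjusted p = 0.591 with an estimated correlation for the cortical and medullary epithelium, natural killer and lymph node lists, 0.360 for interferon, 0.833 for muscle and 0.415 for erythroid genes. Without wild-type replicate 4 these lists were lost except cortical epithelium. They were also lost without stathmin knockout replicate 2 (natural killer, lymph node and erythroid genes), 4 (interferon, medullary and erythroid genes), 5 (muscle and erythroid genes) or 6 (medullary and muscle genes), and without wild-type replicate 1 or 2 (muscle), 3 (muscle and lymph node), 5 (erythroid) or 6 (muscle, erythroid and lymph node). Their adjusted p then reached 0.112 for interferon, 0.214 for natural killer, 0.274 for medullary, 0.835 for muscle, 0.221 for erythroid and 0.279 for lymph node genes. Muscle genes had median log2 ratios of 3.52 and 2.54 in those replicates and from -0.53 to 0.37 in the other 4.

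T cell receptor signalling genes were lower in the stathmin knockout, with 28 of 29 members below 0 and a median of -0.21 (adjusted p = 0.00541, slide-blocked 0.00790, and adjusted p = 0.807 with an estimated correlation). The slide medians ran from -0.84 to 0.33, 4 of 6 below 0. The early response genes Egr1 and Egr2 were at -0.53 and -0.43. Markers of double-positive thymocytes lay alongside, with a median of -0.23 and 17 of 19 below 0, and did not pass (adjusted p = 0.0946), but did without p27 knockout replicates 5 and 6 (adjusted p = 0.00133). Stathmin, tubulin and microtubule genes, the deleted Stmn1 included, were lower as a set (median -0.09, 21 of 34 below 0). Adjusted p was 0.0171 (slide-blocked 0.0270, estimated correlation 0.167), and no test left out Stmn1. In the authors' deposited table the set was upward but did not pass (adjusted p = 0.0536). The slide medians ran from -0.22 to 0.04, 5 of 6 below 0. Tubb5 and Tubb4a, of beta-tubulin, were at -0.70 and -0.56, below 0 on 6 of 6 slides, with Tubb5 at 0.07 in that table, and 1 member fell adjusted over the list alone. This list was lost without stathmin knockout replicate 3 (adjusted p = 0.127) and the receptor signalling list without replicate 1 (adjusted p = 0.0521). G1/S and G2/M genes did not shift (medians -0.000908 and -0.0609, adjusted p = 0.743 and 0.482), and Ccne2, Mcm5, Hmmr, Nuf2 and Cdk2 were at 0.46, -0.19, 0.50, -0.19 and 0.60, with Mcm5 and Nuf2 at 0.21 and 0.13 in the authors' deposited table.

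No gene passed at the gene level between the stathmin knockout and wild type (limma, 0 of 24784, lowest adjusted p = 0.115), and 669 had an unadjusted p under 0.05, fewer than the 1239 chance gives. The spread was estimated over all 4 genotypes, so the outlying p27 knockout replicates 5 and 6 also entered it here. With only these 2 genotypes compared 1 gene passed. The low counts therefore do not show that nothing changed. Under the slide block limma passed 0 and 810 had an unadjusted p under 0.05. It passed 3 genes without p27 knockout replicate 6, and 3 without replicates 5 and 6. Of the lists 12 shifted, 10 up and 2 down, against 11, 4 up and 7 down, with array brightness as a covariate.

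Loss of both proteins was examined against wild type, where 3 genes passed. Hebp1, which encodes a heme-binding protein and lies 4 measured genes from Cdkn1b, rose by 0.92 ± 0.16 (SE), 1.90-fold, from -0.41 ± 0.14 (SD, n = 6) to 0.52 ± 0.31, on 6 of 6 slides (limma adjusted p = 0.0360). Cdkn1b fell as above. A transcript known only by its clone, AK032599, named because so few passed, fell by 2.43 ± 0.40 (adjusted p = 0.0360). Its log2 ratio was 1.12 ± 0.65 (SD, n = 6) in wild type and 2.20 ± 0.84 in the p27 knockout against -1.27 ± 0.77 in the stathmin knockout and -1.31 ± 0.64 in the double knockout. With slide as a block limma passed 0 genes (Hebp1 and AK032599 adjusted p = 0.0583), with 1368 at an unadjusted p under 0.05 against 1162 without the block. The count was 0 without any 1 of 10 mice: wild-type replicates 1, 3, 4, 5 and 6, p27 knockout replicate 3, double knockout replicates 4 and 5, and stathmin knockout replicates 2 and 6. It was 1 without p27 or double knockout replicate 1, 5 without p27 or stathmin knockout replicate 5, 9 without double knockout replicate 3, 17 without p27 knockout replicate 6 and 26 without stathmin knockout replicate 1. Without p27 knockout replicates 5 and 6 it was 49, with 39 up, and held all 3 genes.

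All 11 lists that shifted in the double knockout against wild type shifted up, all 11 also with slide as a block. With array brightness as a covariate 14 shifted, 8 up and 6 down, and of the 11 only adipocyte genes turned (adjusted p = 0.922). Interferon-stimulated genes, the antiviral response, had a median change of 0.36 with 25 of 27 above 0 (camera adjusted p = 1.75e-09, slide-blocked 3.80e-09), on 5 of 6 slides, from -0.15 to 0.77. The antiviral genes Rsad2, Ifih1 and Usp18 were at 0.67, 0.61 and 0.56, and 1 member rose adjusted over the list alone. Erythroid genes had a median of 0.42 with 11 of 12 above 0 (adjusted p = 4.06e-05, slide-blocked 7.56e-05), on 6 of 6 slides from 0.09 to 0.49, led by Slc4a1, the band 3 protein of red cells, at 0.77. Both calls held with an estimated correlation (adjusted p = 0.0232 and 0.0436), the only ones that did in any comparison. In the authors' deposited table the erythroid members Ermap and Epb42 were at -0.21 and -0.29, against 0.61 and 0.59.

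Thymic epithelial genes were higher in the double knockout on 6 of 6 slides. The cortical list had a median of 0.63 (adjusted p = 8.67e-06, slide-blocked 2.71e-05, and adjusted p = 0.311 with an estimated correlation) and slide medians from 0.03 to 0.76. It was led by Foxn1, the master regulator of thymic epithelium, at 1.07 ± 0.27 (SE), and also included the chemokine gene Cxcl12 at 0.63. The medullary list had a median of 0.49 (adjusted p = 3.18e-06, slide-blocked 2.71e-05, and adjusted p = 0.225 with an estimated correlation) and slide medians from 0.14 to 1.28. Its leading genes were Avil at 1.29, Fezf2, a regulator of self-antigen expression, at 1.31 and the milk protein gene Csn2, a tissue-restricted antigen, at 2.19, each above 0 on 6 of 6 slides. No epithelial gene passed over all genes, and 4 cortical and 3 medullary genes rose adjusted over the list alone. Natural killer and gamma delta T cell genes were also higher on 6 of 6 slides (median 0.45, 14 of 14 above 0, adjusted p = 4.06e-05, slide-blocked 3.95e-05, and adjusted p = 0.311 with an estimated correlation), with the granzyme gene Gzmb at 1.14 and the chemokine gene Xcl1 at 1.08.

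Endothelial (median 0.59, adjusted p = 3.18e-06), oxidative phosphorylation (0.21, 6.43e-05), skeletal muscle (0.92, 6.73e-05), mature T cell (0.33, 0.00122), adipocyte (0.29, 0.00667) and dendritic cell genes (0.14, 0.0113) were higher as well. With slide as a block the adjusted p values were 1.84e-06, 4.05e-05, 4.05e-05, 0.00154, 0.00321 and 0.0143, and adjusted p = 0.311, 0.544, 0.544, 0.452, 0.716 and 0.360 with an estimated correlation. Their medians were above 0 on 4, 3, 2, 4, 4 and 4 of 6 slides. Sox17 and the angiopoietin receptor gene Tek were at 1.19 and 0.94, Runx3 at 1.23, and Ctla4 of regulatory T cells at 1.06, but -0.11 in the authors' deposited table. Muscle genes, with Actn3 at 1.67 and Ttn at 1.83, had median log2 ratios of 4.56 and 4.47 in double knockout replicates 2 and 4, 4.00 in wild-type replicate 5 and at most 0.35 in the other 9 mice of the comparison, and the call was lost without double knockout replicate 2 (adjusted p = 0.0662). The adipocyte list was lost without double knockout replicate 4 or wild-type replicate 3, and the dendritic list without wild-type replicate 4 (adjusted p up to 0.111 and 0.0623). Cell cycle lists did not shift (G1/S median -0.01, adjusted p = 0.886, and G2/M median 0.05, adjusted p = 0.407), with Fen1 at 0.27, Rfc3 at 0.24, Hmmr at 0.58 and Ccnb2 at 0.19.

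Loss of stathmin on top of p27 was examined by setting the double against the p27 knockout, the comparison in which the most genes passed. Limma passed 7182 genes, 2404 higher and 4778 lower in the double knockout, and with slide as a block 7974, of which 7011 were shared. Without p27 knockout replicates 5 and 6 it passed 3627, of which 3053 were shared. The p27 knockout arrays were the dimmer ones, and across genes the change correlated by 0.781 with each gene's slope on array brightness within the wild-type and stathmin knockout arrays. With brightness as a covariate 0 genes passed. In the authors' deposited table, 98.6% of the passing genes (12685 of 12861) were higher, against 33.5% here.

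The largest rises included genes of fat and muscle. Scd1 rose by 3.05 ± 0.63 (SE), 8.29-fold, from 1.63 ± 1.30 (SD, n = 5) to 4.69 ± 1.14 (n = 6), and the sarcomere genes Actn3, Actn2 and Pdlim3 and the muscle glycogen phosphorylase gene Pygm rose by 2.84, 2.74, 2.72 and 2.82. Ubxn11, which lies 10 measured genes from Stmn1 on chromosome 4, rose by 2.86 ± 0.42 (adjusted p = 0.00153), the lymphocyte GTPase gene Gimap4 by 2.62 and Podxl, of endothelium, by 2.76. Podxl was at -0.87 (adjusted p = 0.0350) where both channels had to exceed background, a filter that keeps another probe. Without p27 knockout replicates 5 and 6 Actn3, Pygm, Actn2, Pdlim3 and Gimap4 no longer passed (adjusted p = 0.0509, 0.147, 0.104, 0.0607 and 0.0728). The largest falls were Mid1, which encodes a microtubule-associated ubiquitin ligase, by 4.13 ± 0.87, 17.5-fold, and Adgra2, a receptor of vessel growth in the brain, by 4.00 ± 0.83. Ott, Fam171a2, Zfp473, Krtap6-3 (a hair protein), Zfp13 and the growth factor gene Fgf8 fell too (log2 change -3.99, -3.85, -3.73, -3.71, -3.70 and -3.68). The 16 genes had adjusted p from 0.00153 to 0.0322, and from 0.00438 to 0.0249 with slide as a block.

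Of the 27 lists, 18 shifted in the double against the p27 knockout, 17 up and 1 down, and all 18 with slide as a block. Without p27 knockout replicates 5 and 6 there were 10, 8 up and 2 down. The 2 were T cell receptor signalling (median -0.42, adjusted p = 0.00310) and double-positive thymocyte genes (-0.63, 0.00454), which had not shifted on all arrays (medians 0.12 and 0.20). With brightness as a covariate 6 shifted, 2 up and 4 down. None passed with an estimated correlation (adjusted p = 0.528 at the lowest). In the adipocyte list 8 of 24 genes rose (12 adjusted over the list alone) and none fell, with a median of 1.03 (adjusted p = 3.77e-05, slide-blocked 1.52e-05), including Elovl3 by 1.95 and the fatty acid transporter gene Cd36 by 1.97. In oxidative phosphorylation 7 of 32 rose (5 over the list alone) and none fell, with a median of 0.37 (adjusted p = 3.77e-05, slide-blocked 1.53e-05), including Sdha by 1.37 and Atp5a1 by 0.67. The medians were above 0 on 4 of 6 and 5 of 6 slides, and without p27 knockout replicates 5 and 6 they were 0.53 and 0.28 (adjusted p = 0.000515 and 0.000120). Adjusted p = 0.528 with an estimated correlation for both. In the natural killer and gamma delta T cell list 5 of 14 rose, with all 14 above 0 (median 0.83, adjusted p = 0.000598, slide-blocked 0.000677, 6 of 6 slides, 0.528 with an estimated correlation), including Gzmb by 1.82.

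Among thymic stroma, 7 of 17 medullary epithelial genes rose and none fell (median 0.68, adjusted p = 0.00164, slide-blocked 0.00274, 6 of 6 slides), including Trpm5, of tuft cells, by 1.79 and Csn2 by 2.40. In cortical epithelium 4 of 17 rose and 1 fell (median 0.85, adjusted p = 0.00301, slide-blocked 0.00421, 5 of 6 slides), including Foxn1 by 1.36 ± 0.27 (SE) and the Notch ligand gene Dll4 by 1.24. Of the endothelial genes 3 of 18 rose (2 over the list alone) and none fell (median 0.79, adjusted p = 0.00211, slide-blocked 0.00183, 5 of 6 slides), including Tek by 1.67. Adjusted p = 0.528, 0.528 and 0.546 with an estimated correlation for these 3. Fibroblast and extracellular matrix genes were the list that shifted down. Of 24 genes 13 fell and none rose (16 and 1 over the list alone), with a median of -1.02 (adjusted p = 0.00301, slide-blocked 0.00293, and adjusted p = 0.640 with an estimated correlation). In the authors' deposited table the list's direction was upward but did not pass (adjusted p = 0.129). Serpinf1, Fbln2 and the protease inhibitor gene Timp1 fell (log2 change -1.60, -1.44 and -1.34), but stood at 0.28, 0.34 and 0.33 in that table. The slide medians ran from -2.77 to -0.41, and the call was lost without p27 knockout replicate 6 (adjusted p = 0.0514) and without replicates 5 and 6 (median -0.45, adjusted p = 0.190). The cortical list was lost in the same way (adjusted p = 0.140 and 0.0671). With array brightness as a covariate fibroblast genes were higher in the double knockout (adjusted p = 0.000720), and macrophage and G1/S genes lower (adjusted p = 0.00568 and 0.0399).

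Blood cell lists were higher in the double knockout as sets. Mature T cell genes had a median of 0.62 (6 of 18 rose, adjusted p = 0.00283), double-negative thymocyte genes 0.52 (4 rose and 1 fell of 18, 0.00659), dendritic cell genes 0.51 (3 rose and 1 fell of 19, 0.0315), macrophage genes 0.53 (3 rose and 1 fell of 20, 0.0326), B cell genes 0.45 (1 of 18 rose, 0.0315) and erythroid genes 0.46 (2 of 12 rose, 0.00756). With slide as a block the adjusted p values were 0.00293, 0.00898, 0.0309, 0.0318, 0.0309 and 0.00898, and the medians were above 0 on 6, 4, 5, 4, 5 and 5 of 6 slides. Adjusted p = 0.528, 0.549, 0.528, 0.640, 0.647 and 0.528 with an estimated correlation. Runx3 rose by 2.41 ± 0.36 (SE), 5.30-fold, and lies 10 measured genes from Stmn1. Ctla4 and Slfn1 of T cells rose by 2.05 and 2.20, Spi1 and the Notch targets Hes1 and Nrarp by 2.15, 1.82 and 1.94, Clec9a of dendritic cells by 1.48 and the complement gene C1qa of macrophages by 1.70. All but the erythroid list were lost without p27 knockout replicate 6, macrophage genes also without double knockout replicate 1 or 2, and B cell genes without p27 knockout replicate 3 or double knockout replicate 4 (adjusted p = 0.0619, 0.226, 0.228, 0.247 and 0.0862 at the highest over single mice left out). Interferon-stimulated genes (median 0.37, 6 rose and 2 fell of 27, adjusted p = 0.00560, slide-blocked 0.00632, 5 of 6 slides) held, with Irf7 and Isg20 rising by 1.93 and 1.86 (adjusted p = 0.528 with an estimated correlation). Skeletal muscle genes had a median of 1.32 (3 rose and 1 fell of 22, adjusted p = 0.00301, slide-blocked 0.00293, and adjusted p = 0.640 with an estimated correlation) and slide medians above 0 on 3 of 6.

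The proliferation lists moved little. Of the G1/S genes 4 of 36 rose and 2 fell (2 and 2 over the list alone), with a median of 0.16 (adjusted p = 0.0426, slide-blocked 0.0441, and adjusted p = 0.760 with an estimated correlation), and the median was above 0 on 1 of 6 slides, from -0.41 to 1.90. Cdc45, Pcna and Rfc3, of the replication fork, rose by 1.96, 1.08 and 0.74, while E2f1 and Ccne1 fell (-0.76 and -0.70) but stood at 0.92 and 0.68 in the authors' deposited table. Of the G2/M genes 4 of 38 rose (1 over the list alone), with a median of 0.18 (adjusted p = 0.0315, slide-blocked 0.0308, and adjusted p = 0.707 with an estimated correlation) and slide medians above 0 on 2 of 6, led by Hmmr, Anln and Ttk with rises of 1.82, 1.29 and 0.97. Ribosomal protein genes had a median of 0.28 (2 rose and 2 fell of 30, adjusted p = 0.0102, slide-blocked 0.0112, 5 of 6 slides, adjusted p = 0.549 with an estimated correlation). In the authors' deposited table their direction was downward but did not pass (adjusted p = 0.224). These 3 lists were lost without p27 knockout replicate 6, and the G1/S and G2/M lists also without double knockout replicate 1 or 5 (adjusted p = 0.532, 0.633 and 0.0830 at the highest), and without replicates 5 and 6 the G1/S and G2/M medians were -0.27 and -0.17 (adjusted p = 0.288 and 0.900). Of 32 cyclin-dependent kinases, cyclins and inhibitors 1 rose and 6 fell, with no shift (median -0.08, adjusted p = 0.917). Cdk2 rose by 2.41 ± 0.54 (SE), and the inhibitor gene Cdkn2a fell by 1.84 ± 0.44 but stood at 0.26 in the authors' deposited table. Of 34 stathmin, tubulin and microtubule genes 5 rose and 5 fell (5 and 6 over the list alone), with no shift (median -0.20, adjusted p = 0.917). Stmn4 of the stathmin family fell by 3.46 ± 0.78 and Tubb3 by 1.32 ± 0.35, the latter at 0.55 in that table.

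Loss of p27 on top of stathmin was examined by setting the double against the stathmin knockout. Klra10 and Cdkn1b were the 2 genes that passed, both lower in the double knockout. Klra10 fell by 3.17 ± 0.46 (SE), 9.02-fold, from 4.27 ± 0.94 (SD, n = 6) to 1.09 ± 1.17 (n = 6), on 6 of 6 slides by -4.42 to -1.27 (limma adjusted p = 0.0101, and 0.0419 with slide as a block, the only gene past the threshold there). Double knockout replicate 2 stood apart, at 3.37 for Klra10, the wild-type level (3.36 ± 0.62), and at 0.97 on Cdkn1b probe A_51_P146126 (4 others -1.41 to -0.61). That Cdkn1b value was near the highest of the p27 knockout (0.99) and below the lowest of wild type (1.37) and stathmin knockout (1.21). This mouse's A_51_P169173 value, -0.25 and not well above background, was also below both (-0.21 and -0.17). By Klra10 its p27 loss stays in doubt, and it was kept as labelled. Stathmin knockout replicate 1 also stood apart, at 2.37 for Klra10. Of 24784 genes 315 had an unadjusted p under 0.05, and 377 with slide as a block. The count was 0 without double knockout replicate 3, 4 or 5 or stathmin knockout replicate 4 or 6, 3 without double knockout replicate 2, stathmin knockout replicate 1 or wild-type replicate 4, and 1 without p27 knockout replicates 5 and 6. It was also 1 without wild-type or p27 knockout replicate 2 or 3, wild-type replicate 6, double knockout replicate 6 or stathmin knockout replicate 2, 3 or 5.

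Of the 27 lists 14 shifted between the double and stathmin knockouts, 11 up and 3 down (15 with slide as a block, histones added), with no single member past the threshold over all genes or over any list alone, apart from Cdkn1b. Adipocyte genes were lower (median -0.65, 22 of 24 below 0, adjusted p = 6.02e-10, slide-blocked 2.46e-11, 5 of 6 slides, and adjusted p = 0.242 with an estimated correlation), with Lpl, the lipoprotein lipase gene, at -1.15 and Scd1 at -1.15 (0.20 in the authors' deposited table). Oxidative phosphorylation genes were lower (median -0.22, 29 of 32 below 0, adjusted p = 2.58e-09, slide-blocked 1.63e-09, 5 of 6 slides, and adjusted p = 0.269 with an estimated correlation), but higher than other genes in the authors' deposited table (adjusted p = 0.00862). Ndufb5 and Cox7b were at -0.49 and -0.48, with Cox7b at 0.10 in that table. Lymph node stroma genes were lower (median -0.32, adjusted p = 0.0167, slide-blocked 0.0131, 4 of 6 slides, and adjusted p = 0.604 with an estimated correlation).

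Higher in the double than in the stathmin knockout were interferon-stimulated genes (median 0.27, adjusted p = 1.03e-06, slide-blocked 1.20e-06, 5 of 6 slides), with Oas3 at 0.56, medullary epithelium (0.14, 0.000203, 0.00103, 5 of 6), with Fezf2 at 0.95, and cortical epithelium (0.17, 0.00903, 0.0125, 5 of 6), with Foxn1 at 0.75. Mature T cell (0.22, 0.00247, 0.00352), stress response (0.16, 0.00270, 0.00707), erythroid (0.27, 0.00270, 0.0107), dendritic cell (0.09, 0.00903, 0.0125), muscle (0.39, 0.0133, 0.0131), stathmin and tubulin (0.13, 0.0167, 0.0147), natural killer (0.24, 0.0180, 0.0153) and G2/M genes (0.07, 0.0200, 0.0197) followed, in the same order of values. Adjusted p = 0.128, 0.269, 0.574, 0.411, 0.242, 0.222, 0.269, 0.712, 0.222, 0.604 and 0.712 with an estimated correlation for these 11. The heat shock gene Hspa1a was at 0.97 and Hspa8 at 0.60 (-0.03 in the authors' deposited table), and Foxm1 and Ccnb2 of mitosis at 0.27 and 0.21. The stress list was lost without double knockout replicate 2 (adjusted p = 0.191). Among the stathmin knockout mice, leaving out replicate 1 ended the natural killer, mature T, dendritic, muscle and G2/M calls, replicate 2 the cortical, muscle, G2/M and lymph node calls, and replicate 3 the natural killer, dendritic, muscle and stathmin and tubulin calls. Replicate 4 ended the muscle, 5 the G2/M and lymph node and 6 the G2/M call. Among the double knockout mice, replicate 1 ended the natural killer, G2/M, lymph node and stathmin and tubulin calls, replicate 2 the muscle and stathmin and tubulin calls, replicate 3 the lymph node, 4 the muscle, 5 the G2/M and lymph node and 6 the natural killer call. The adjusted p then reached 0.672 for natural killer, 0.0711 for mature T, 0.198 for dendritic, 0.0678 for cortical, 0.170 for stathmin and tubulin, 0.859 for muscle, 0.410 for G2/M and 0.554 for lymph node genes.

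Whether the loss of both proteins had an effect beyond the sum of the single losses was tested as an interaction. Limma passed 0 of 24784 genes (lowest adjusted p = 0.262), 4433 had an unadjusted p under 0.05, and 0 passed with slide as a block or without p27 knockout replicates 5 and 6. Of the lists 10 passed, 9 above and 1 below additivity, and 0 with an estimated correlation (adjusted p = 0.703 at the lowest) or without p27 knockout replicates 5 and 6. In none of the 5 comparisons did cyclin-dependent kinase, p53 target or parathyroid and thyroid genes shift. The p53 targets were at a median of 0.50 in the p27 knockout against wild type (adjusted p = 0.178), and histones at 0.13 in the double against the stathmin knockout (adjusted p = 0.0505), where they shifted up with slide as a block (adjusted p = 0.0222, and adjusted p = 0.664 with an estimated correlation).

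The changes from wild type were compared across genes, which are not independent replicates. Changes in the stathmin and double knockouts correlated by 0.764, with 75.4% of genes of the same sign, and those in the p27 knockout by -0.263 with the stathmin knockout (44.6%) and -0.409 with the double knockout (37.4%). Unchanged groups and a shared control drawn from all genotypes gave 0.451 ± 0.281 (SD over 100 simulations) with 65.4% of the same sign. Covariance less its simulated value (SD 0.0747) was 0.0252 for stathmin and double, -0.118 for p27 and stathmin and -0.163 for p27 and double knockouts. With separate wild-type mice for each side, the correlations were 0.0629 and 0.273, -0.626 and 0.0149, and -0.683 and -0.137 in that order. These sets were wild-type replicates 1 to 3 and 4 to 6, which shared no slide and differed in sex by Xist and Ddx3y. The values thus also hold differences of slide and sex, and do not decide how far the changes agree. No gene passed in more than 1 of the 3 comparisons, where independent lists would share 0.000161 between the p27 and double knockouts.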

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

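The tests without p27 knockout replicates 5 and 6, with brightness as a covariate and with slide as a block together with array weights were chosen only after the result was seen. Single mice far from the other 5 of their genotype were sought by Dixon's gap test, and chance marks about 1 in 20 such groups of values.

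P27 knockout replicate 6 stood apart most often. Its mean correlation with the other p27 knockout arrays was 0.321 (others 0.646 to 0.768). Its median log2 ratio was -0.61 for G1/S genes (others 1.32 to 1.75), -0.25 for G2/M genes (0.98 to 1.29), -0.24 for histones (0.91 to 1.39), -0.0633 for T cell receptor signalling (4.61 to 5.57), 0.0775 for double-positive thymocytes (5.24 to 6.17), -0.63 for double-negative thymocytes (1.23 to 2.03) and 0.0418 for cortical epithelium (2.66 to 3.03). Its Stmn1 probe A_51_P495641 read -0.76 (others 3.20 to 4.09), and on Stmn1 probe A_52_P319161 it was p27 knockout replicate 5 that lay far off, at 0.80 (others 2.33 to 3.22). P27 knockout replicate 2 had a muscle median of 1.23 (others -0.63 to -0.31).

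Among the other genotypes, stathmin knockout replicate 1 had a spread of log2 ratios of 1.18 (others 1.51 to 1.58) and a natural killer median of 1.46 (2.63 to 2.98), and stathmin knockout replicate 3 a mean correlation of 0.848 with its own genotype (0.896 to 0.919). Stathmin knockout replicate 4 had an interferon median of -0.0233 (-0.39 to -0.28). Double knockout replicate 1 had a cyclin-dependent kinase median of 0.74 (0.28 to 0.45), replicate 2 a stress median of -0.20 (-1.34 to -0.96) and replicate 3 a natural killer median of 1.94 (2.74 to 3.15). Wild-type replicate 5 had a muscle median of 4.00 (-0.83 to 0.09). In all, 14 of 108 list medians stood apart where 5.4 would by chance, 3 of 20 array measures (1 by chance), 2 of 18 values of the targeted genes (0.9) and 48 of 584 values of the named genes (29.2).

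The double knockout departed from the sum of the single knockouts in 10 lists, a difference between groups tested by the interaction. The adjusted p was 0.0341 for G1/S, 0.0124 for G2/M, 0.00319 for ribosomal proteins, 0.0244 for double-positive and 0.0214 for double-negative thymocytes, 0.00588 for mature T cells, 0.0123 for natural killer cells, 0.0124 for medullary epithelium, 0.0374 for muscle and 0.00267 for fibroblasts. None passed with an estimated correlation (adjusted p = 0.703 at the lowest) or without p27 knockout replicates 5 and 6.

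The 7182 genes that separated the double from the p27 knockout invite 3 explanations. The tables argue against p27 knockout replicates 5 and 6 as the whole source, because 3627 genes passed without them. Lower Cy5 signal on the p27 knockout arrays may contribute: across genes the change correlated by 0.781 with each gene's slope on brightness within wild-type and stathmin knockout arrays, 3 of 100 shuffles of brightness gave as high a value, and 95.9% of the 7182 genes had the sign of that slope. Loss of stathmin also stays open, since the change correlated by 0.521 with that from wild type to stathmin knockout, with no array shared, and by 0.176 once the brightness slope was removed. Both stay open together, and array position, which follows genotype, was not tested.

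Other splits of the 12 mice of each pair into 6 and 6 (100 drawn of 462) were counted against the real ones. Chance can be excluded for the double against the p27 knockout, where 1 of 100 splits, the real one, gave as many genes (7182 real, 1669 the highest other). By this count alone it would be excluded also for the double knockout against wild type (2 of 100 splits, 3 real, 24 the highest other) and against the stathmin knockout (2 of 100, 2 real, 325 the highest other). But the few genes include the deleted Cdkn1b itself and its neighbours Hebp1 or Klra10, and other splits called more. In these 2 comparisons the count thus does not exclude chance for other genes. These splits took no account of the slides, and with slide as a block 0 and 1 genes passed there. Chance cannot be excluded for the p27 knockout against wild type (6 of 100, 2 real, 1136 the highest other). For the stathmin knockout against wild type and the interaction the real count was 0, which every split reaches (100 of 100 each, 249 and 0 the highest other), so the splits test nothing there. Splits that call 24, 325, 1136 or 249 genes, several times the real count, point to a structure of the samples other than genotype. For gene lists chance can be excluded in no comparison. As many lists shifted in 47 of 100 splits for the p27 knockout (12 real, 21 the highest other), 29 for the stathmin knockout (12 and 17) and 38 for the double knockout against wild type (11 and 20), 9 for the double against the p27 knockout (18 and 20) and 15 for the double against the stathmin knockout (14 and 17).

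Splits along slides, 3 against 3, gave at most 63 genes between p27 knockout and wild-type arrays (slides 1, 4 and 6 against the rest), above the real 2, and 0 genes passed with slide as a block. In the other 4 pairs they gave at most 2 genes, but slides 1, 2 and 6 against the rest, which differ in Ddx3y, gave 0 there, so a low count says little about slides. They shifted up to 19, 16, 13, 17 and 15 lists in the comparisons in the order of the report, at or above the real count in all but the double against the p27 knockout, and with slide as a block 12, 12, 11, 18 and 15 lists shifted.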

How the results depend on the processing

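The settings without p27 knockout replicates 5 and 6, with brightness as a covariate and with slide as a block plus array weights were chosen only after the result was seen. Counts of genes are given in the order p27, stathmin and double knockout against wild type, then double against p27 and against stathmin knockout (2, 0, 3, 7182 and 2 in the report), and lists likewise (12, 12, 11, 18 and 14). The cause was not tested, except where fewer arrays or probes entered.

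Without background correction 9, 1, 7 and 5 genes passed (double against p27 within 1.5 times), and Cdkn1b probe A_51_P146126 passed in the double against the stathmin knockout (-2.16). With Agilent's ratios 1 gene passed for the stathmin and 6 for the double knockout against wild type, that probe passed against the stathmin knockout (-2.21) and A_51_P169173 in the p27 knockout (-3.00). With Cy5 alone 7, 1, 5 and 6 genes passed. The dim Cdkn1b probe A_52_P673863 changed sign without background correction (0.0138 and 0.0258 for the double against wild type and stathmin knockout), with Cy5 alone (0.15 and 0.16) and with Agilent's ratios (0.25 against the stathmin knockout).

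In the authors' deposited table, 4445, 1, 12861 and 1 genes passed (stathmin knockout 0 as in the report), and 98.6% of those in the double against the p27 knockout were higher, against 33.5% in the report, 42.5% with Cy5 alone and 36.7% with Agilent's ratios. Cdkn1b probes passed in the p27 knockout (-1.13 and -1.07) and not in the double knockout (-0.46), and Stmn1 probe A_51_P495641 stood at 0.112, 0.0843 and 0.438 in the stathmin and double knockout against wild type and the double against the p27 knockout. Of the named genes, 43 values changed sign there. They were, for the p27 knockout, Rpl5 0.0524, Pdgfrb -0.38, Serpinf1 -0.0474, Fn1 -0.0578, Ccne1 -0.44, E2f1 -0.65, Foxm1 -0.54, Tubb6 -0.16 and Tubb3 -0.30. For the stathmin knockout they were Cdkn1b 0.0602, Stmn1 0.11, Tubb5 0.0665, Nr4a1 0.0694, Atp5b -0.0143, Klf1 -0.0304, Mcm5 0.21 and Nuf2 0.13, and for the double knockout against wild type Stmn1 0.0843, Ctla4 -0.11, Clec9a -0.29, Ermap -0.21, Epb42 -0.29 and Tubb5 0.11. Against the p27 knockout they were Cdkn1b 0.68, Stmn1 0.44, Fbln2 0.34, Serpinf1 0.28, Timp1 0.33, E2f1 0.92, Ccne1 0.68, Cdkn2a 0.26 and Tubb3 0.55. Against the stathmin knockout they were Hspa8 -0.0341, Cox7b 0.10, Slfn1 -0.0631, Ctla4 -0.26, Prf1 -0.0844, Trpm5 -0.21, Flt3 -0.14, Scd1 0.20, Epb42 -0.57, Ermap -0.25 and Ccnh 0.0350. Elsewhere 3 changed sign: Xcl1 against the stathmin knockout with Agilent's ratios (-0.0369), Podxl with both channels above background (-0.87) and Cdkn1b in the stathmin knockout with the mean of its probes (0.12).

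With both channels above background 0 genes passed for the p27 knockout and 0 for the double against the stathmin knockout, and 4 and 11 lists shifted for the p27 knockout and the double against it. With the mean of a gene's probes 1, 6 and 1 genes passed for the stathmin, the double and the double against the stathmin knockout. With only the 2 genotypes compared 1, 37, 3532 and 0 genes passed in the last 4 comparisons. Stmn1 probe A_51_P495641 then passed (-1.54 and -1.67) and Cdkn1b did not (-2.30, double against wild type). With array weights 2738, 7, 355 and 16 genes passed outside the double against the p27 knockout, and 4 and 11 lists shifted for the p27 knockout and the double against it. Cdkn1b then passed at -1.64 and -2.09 (A_51_P146126, p27 against wild type and double against stathmin knockout) and at -1.26, -1.17 and -1.47 (A_51_P169173), and Stmn1 probe A_51_P495641 at -1.67, -1.82 and -1.70.

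With slide as a block 0, 0 and 1 genes passed (p27 and double knockout, double against stathmin knockout) and Cdkn1b did not (-2.30, double against wild type); with scan day as a block 4 passed for the p27 knockout and 1 for the double against the stathmin knockout. With an estimated correlation 0, 0, 2, 0 and 0 lists shifted. Same-numbered wild-type, stathmin knockout and double knockout mice shared a slide, so for these 3 genotypes the number is the slide; only the p27 knockout numbers differ. Deviations of same-numbered mice correlated between -0.554 and 0.614, and at most 4 of 6 mice correlated best with their own number. With the replicate number as a block 1 gene each passed for the stathmin and double knockout against wild type and the double against the stathmin knockout, and Cdkn1b probe A_51_P146126 did not (-2.30). It changed no other count by over 1.5 times and no other call of a targeted gene.

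Without p27 knockout replicates 5 and 6, 4, 3, 49, 3627 and 1 genes passed and 8, 14, 14, 10 and 15 lists shifted (4, 11, 12, 8 and 12 up). With brightness as a covariate 0, 5 and 0 genes passed (p27 and double knockout against wild type, double against p27), 1, 11, 14, 6 and 14 lists shifted (1, 4, 8, 2 and 10 of them up), and the correlation of p27 knockout changes with those of the stathmin and double knockouts became 0.0686 and -0.0643. With slide as a block plus weights 4485, 14, 286, 10777 and 8 genes passed, and 7 lists shifted for the p27 and 7 for the stathmin knockout.

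Leaving out each array in turn gave counts of 0 to 2833, 0 to 3, 0 to 26, 5352 to 8425 and 0 to 3 genes and of 6 to 13, 7 to 15, 10 to 14, 10 to 19 and 10 to 16 lists, with 0 genes for the interaction throughout. The lowest list counts came without p27 knockout replicate 6 (6 and 10) and wild-type replicate 4 (7), and the highest gene counts without p27 knockout replicate 4 (2833 and 8425), p27 knockout replicate 6 (3) and stathmin knockout replicate 1 (26). Of 253 values of named genes, all 253 kept their direction and side of the threshold without background correction and with no filter on dim probes, 252 with scan day, 246 with slide and 246 with replicate number as a block, 245 with Agilent's ratios, 243 with Cy5 alone and 171 in the authors' deposited table. Aquantile scaling leaves the log ratios as they are and so tests nothing. Signal over background limits the dim probes.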

Other observations

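The tests of genes around Cdkn1b and Stmn1 and of natural killer cells, with their bounds, and the choice of AK032599, Xist and Ddx3y, were made only after the result was seen.

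Genes beside Cdkn1b on chromosome 6 differed between the p27 knockout and wild type and between the double and stathmin knockouts. Among 101 genes around Cdkn1b, itself included, 10 were among the 100 genes of lowest p in the p27 knockout against wild type and 11 in the double against the stathmin knockout, where 0.594 would be by chance, against 1 in each of the comparisons in which both or neither genotype lacked p27. The double knockout against wild type, in which 1 genotype also lacked p27, held 5 (4 besides Cdkn1b, with 4 in the highest other window). Some natural killer receptor genes of this region were lower without p27 in the first 2 comparisons, Klra10 by -2.83 and -3.17, Klra9 by -2.63 and -2.07, Klra8 by -1.81 and -1.49 and Klrc1 by -2.71 and -1.18. Others were not, with Klrk1 at -0.07 and 0.19, Klra17 at -0.03 and 0.50 and Klre1 at 0.10 and -0.02. In the double knockout against wild type Klra10 was at -2.26 and Klrc1 at -0.11. In the same first 2 Emp1, of epithelial membranes, stood at 1.19 and 1.06 and Hebp1 at 0.85 and 0.64. Beside Stmn1 on chromosome 4, Ubxn11 and Hmgn2 stood at 1.54 and 1.22 in the stathmin knockout against wild type and at 2.86 and 2.08 in the double against the p27 knockout, and Rpl11 at -1.01 and -1.16.

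A candidate explanation for the Cdkn1b region is DNA of another strain kept beside the deleted gene when the mutation was crossed into C57BL/6, which the sources used here do not describe. The 9 and 10 neighbours in this window, Cdkn1b not counted, compare with at most 2 and 4 genes in any other window of the genome outside the region, and Ly49 genes are known to differ between strains. If the Klra8, Klra9 and Klra10 probes read separate genes (not tested), the values argue against an effect on the nearest genes only. Of the 14 neighbours, 11 lay beyond the 10 nearest on their side. These 3 of the 11 were found in both comparisons, which share no array, against at most 1 elsewhere. The values also argue against fewer natural killer cells. In the double against the stathmin knockout the median of the 14 natural killer and gamma delta T cell genes was 0.239 (SD of members 0.298, 13 of 14 above 0) while Klra10 was at -3.17. That list was at 0.45 in the double knockout against wild type, with 14 of 14 above 0. It was at -0.47 in the p27 knockout against wild type, with 5 of 14 above 0. It was at 0.0277 there without p27 knockout replicates 5 and 6 (SD of members 0.341, the lowest at -0.58), while Klra10 and Klra9 stayed at -2.74 and -2.58. An effect of p27 on the receptor genes themselves was not tested and stays open, as does cross-strain hybridisation of the probes.

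For Stmn1 strain DNA stays open. The window held 4 genes in the double against the p27 knockout (5 in the highest other window), where 7182 genes passed and the lowest 100 single out no region, and 4 besides Stmn1 in the stathmin knockout against wild type (also 4 in the highest other), so it did not stand out in either. An effect on the nearest genes only stays open too, since no excess of changed neighbours was shown in either comparison. Of 5 neighbours 2 lay beyond the 10 nearest, Hmgn2 at 13 and Rpl11 at 30 genes away, and both were found in both comparisons with the same sign, against at most 1 such gene elsewhere. That margin is small, and the changes of these 2 comparisons correlated by 0.521 across all genes, so it does not decide. For Ubxn11, at 10 genes away, that effect was not tested apart. AK032599, a transcript the annotation used here did not place, was at -2.39 in the stathmin knockout against wild type, -2.43 in the double knockout and -3.52 in the double against the p27 knockout, and 1.09 in the p27 knockout.

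Xist and the Y-linked Ddx3y split the arrays by slide. Xist log2 ratios were -0.58 to 1.85 on slides 1, 2 and 6 and -2.94 to -1.01 on slides 3, 4 and 5, for all 4 arrays of each slide. Ddx3y was -8.12 to -3.41 on the former slides and 0.09 to 1.28 on the latter. By these genes the mice on slides 1, 2 and 6 read as female and those on slides 3, 4 and 5 as male. Each genotype then has 3 females and 3 males, the numbers in the labels. Sex thus went with slide, and slide as a block also takes up a difference between the sexes.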
